A study of Arabidopsis thaliana with 57 samples.

How the data were processed

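RNA was sequenced from rosette leaves of the Arabidopsis thaliana accession Col-0, the usual laboratory wild type, harvested at 18 days of age during the light period. Per the labels' protocols, plants grew at 22 °C by day and 18 °C by night under 120 µmol m-2 s-1 of light. In the end-point setup a stress began on day 15 and leaves were taken at its end. In the recovery setup it began on day 12 and was followed by 3 days in standard conditions. Heat meant 27 °C by day and 23 °C by night, high light 350 µmol m-2 s-1, drought a shortage of water, and humidity trays that were sealed with an excess of water. Cold meant 12 °C by day and 8 °C by night, at 80 µmol m-2 s-1 (cold) or 200 µmol m-2 s-1 (cold with high light). Heat-drought and heat-high light were combinations of these conditions.

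The authors deposited a single table of regularized log values (rlog), a log2 scale that pulls genes with few reads towards their mean over the libraries. Per the submitters' processing notes, the authors used Trimmomatic, STAR, featureCounts and DESeq2 with the genome build TAIR10, and no versions are given in the sources used here. Read counts were not used here, so the depth of each library is unknown and no interval or detection limit was drawn from it. Because of the pull towards the mean, a difference of a weakly expressed gene can be understated. Some values went the other way: CYP71A15 stood at 27.0 in heat-drought end-point replicate 3, with a median of 3.24 in the other libraries. Whether the counting used strand is not given, so genes that overlap on opposite strands, and near-identical copies such as the LHCB1 genes, are uncertain as single genes.

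The table holds 28775 genes. Names matched 51 of its columns to 51 of the 57 samples of the series, which fall in 17 groups of 3 libraries: a control group and, for each of 8 stresses, an end-point and a recovery group. Another 6 columns of per-sample values could not be matched to a sample by name and were not used. The group that combines heat, drought and high light was therefore not analysed here, nor was the planned test of drought by high light within heat, and plans written for 57 libraries, 19 groups and 9 stresses were run on 51, 17 and 8. The only control group comes from the recovery setup, and every comparison with a control uses its 3 libraries. Nothing in the labels says that replicates come from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicate libraries correlated across genes with r from 0.980 to 0.998, and 0 pairs of libraries held identical values.

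Of the 28775 genes, 2657 were listed at 0 in every library used, and the 19010 with a mean rlog of at least 3 were tested. Differences were tested in R 4.3.3 with limma 3.58.1, with data.table (version 1.17.8) for reading, with 1 mean per group over all 51 libraries, a moderated two-sided test with an intensity trend and robust variances, and Benjamini-Hochberg adjustment per comparison at 0.05. The comparisons were each end-point with the control, each recovery with the control, each recovery with its end-point, the interaction of heat with drought, the interaction of heat with high light, and cold with high light against cold. A gene with a difference of at least 1 on the log2 scale at the end-point was called returned when its recovery differed from the end-point towards the control and did not pass against the control, kept when its recovery differed from the control in the same direction, and crossed when in the opposite direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

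Library medians differed between groups, so each library was also centred on its median over the genes tested. Unless a sentence says that values are as deposited, differences of single genes are given relative to the library median, on the log2 scale with their standard error (SE), n = 3 libraries per group, and a named gene passed limma's test at an adjusted p of 0.05 both as deposited and relative to the median unless stated. Counts of genes are given as deposited, the form chosen before the data were examined, and relative to the median.

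Gene lists written before the data were examined were tested with camera, using a correlation between genes estimated for each list and Benjamini-Hochberg adjustment over lists and stresses within a family of comparisons, 168 tests for the end-points. The 21 lists with at least 3 members kept cover the cold regulon, abscisic acid and drought, heat shock, endoplasmic reticulum folding, hypoxia, jasmonate, salicylic acid defence, senescence and starvation, starch and sugar, flavonoid and anthocyanin, glucosinolate synthesis, photoprotection and oxidative stress, light harvesting, the circadian clock, flowering, the cell cycle, thermomorphogenesis and auxin, chloroplast-encoded and mitochondrion-encoded genes, and markers of guard cells and of phloem. Marker lists of shoot meristem, root and flower kept fewer than 3 members and were not tested as lists. Of 283 members written, 6 were dropped because the reference gave the identifier another name. Counts adjusted over the list alone use the values as deposited.

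Genes were named by a rule written before the data were examined: the 5 largest positive and 5 largest negative differences as deposited among genes past the threshold with a symbol whose 3 stress libraries all lay beyond all 3 control libraries (3 in each direction for recovery against end-point, 4 for combinations), an arrangement that chance gives for 10% of unchanged genes in either direction. Up to 4 members of a described list were taken by the size of their difference. Symbols came from the gene table of assembly TAIR10.1, which matched 28009 of the 28775 identifiers. Its coordinates were not used because the table was made on TAIR10.

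Alternatives fixed at the same time were no filter, a mean rlog of at least 5, the replicate number as a block, limma without trend and robust variances, quantile normalization, centring, each replicate left out in turn, a fit on the groups compared only, a preset correlation of 0.01 in camera, no minimum difference for the classes, and calls in at least 7 of 8 end-points (written as 8 of 9). A weight per group, a fit without the 2 libraries that stood apart, and groups-only fits of the combinations were chosen after seeing the data. Comparisons with the same controls were set beside simulated unchanged groups, whose shared controls were simulated too, from residuals of all groups. The procedure was tested on simulated data in which 200 of 19010 genes were changed. Residuals of all libraries were shuffled over the groups, so simulated groups had about the same spread. Spreads of the real groups differed, with weights from 0.317 in recovery from cold with high light to 2.12 in recovery from humidity. The shares that follow therefore need not hold for a single real comparison. For drought end-point against control it called 95.2% of changes of 1 on the log2 scale with 1 false call, for drought recovery against control 94.5% with 0 false calls and 57.9% of changes of 0.5, and for the interaction of heat and drought 90.4% of changes of 1.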

Results

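The series asks how far responses of the leaf transcriptome to abiotic stress revert once the stress ends. Values of 19010 genes were compared in 51 rosette libraries, 3 from control plants and 3 from each end-point and each recovery group of 8 stresses. The depth of the libraries is unknown, since the values are log2 rlog values and not counts. Before any comparison, the median over genes was higher than in the control by 0.73 at the end-point of heat-drought, 0.54 in drought, 0.51 in cold with high light, 0.34 in cold and 0.13 in high light, and by 0.12 in recovery from drought and 0.10 in recovery from high light. In the remaining 9 groups it lay within about 0.1 of the control. Differences below are therefore relative to the library median. Centring takes the same amount from every gene of a library, but weakly expressed genes rose less as deposited. In the lowest quartile of mean expression the median difference was 0.18 in drought and 0.24 in heat-drought, against 0.57 and 0.83 in the third quartile. A weakly expressed gene can therefore be lower relative to the median through the centring alone. As deposited, 10312 of all 19010 genes passed as higher at the end-point of cold, 12963 in cold with high light, 11675 in drought and 12684 in heat-drought. List counts as deposited or adjusted over the list alone include this shift and are to be read beside these counts.

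**Figure D1:**
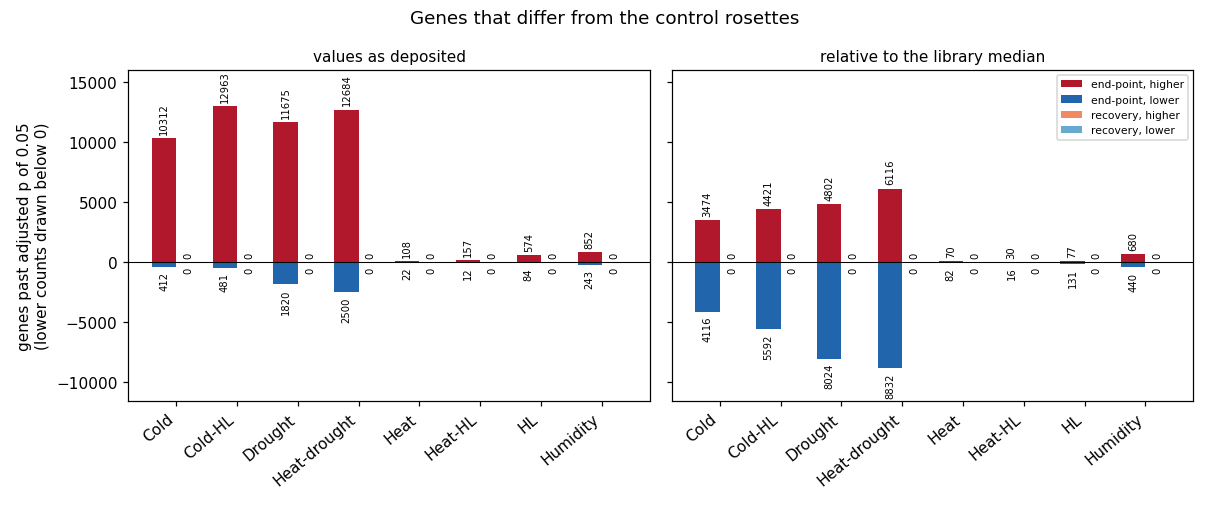
Number of genes past limma's adjusted p of 0.05 against the control for each stress (x axis), with higher genes above and lower genes below 0, at the end-point and after recovery, as deposited (left) and relative to the library median (right). Cold and drought treatments changed between 7590 and 15184 genes at the end-point, the other stresses at most 1120, and recovery 0.

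Cold at low light was marked by a rise of cold acclimation genes. KIN1 (AT5G15960) rose by 4.53 ± 0.46 (SE), 23.1-fold, and COR15B (AT2G42530) by 3.38 ± 0.48, both encoding small proteins that protect cells in the cold. Among 17 genes of the cold regulon 15 rose, 0 fell and 2 did not pass as deposited, 15 and 0 adjusted over the list alone, and 11 rose and 0 fell relative to the median (adjusted p = 0.566 with an estimated correlation). COR15A rose by 3.20 ± 0.38 and LTI30, a dehydrin, by 2.08 ± 0.48. Flavonoid genes rose as well, 14 of 16 with 0 falling as deposited and adjusted over the list alone, and 13 with 1 falling relative to the median (adjusted p = 0.566 with an estimated correlation). TT4, the chalcone synthase at the entry of the pathway, rose by 2.07 ± 0.22, and DFR, an enzyme of its anthocyanin branch, by 1.44 ± 0.30.

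Clock genes shifted at the hour of harvest in cold, 11 of 15 rising and 2 falling as deposited and adjusted over the list alone, and 9 and 2 relative to the median (adjusted p = 0.574 with an estimated correlation). FKF1, a blue light receptor of the clock, was higher by 2.77 ± 0.35 and PRR5 by 2.33 ± 0.30. Of 16 photoprotection genes 8 rose and 1 fell as deposited and adjusted over the list alone, but 3 and 1 relative to the median (adjusted p = 0.923 with an estimated correlation), among them the early light-induced proteins ELIP1 (AT3G22840), by 4.45 ± 0.52, and ELIP2, by 3.79 ± 0.48. Genes of elongation growth fell. The thermomorphogenesis and auxin list had 1 member rising and 7 falling of 13 as deposited and adjusted over the list alone, and 0 and 11 relative to the median (adjusted p = 0.00631 with an estimated correlation, 0.221 relative to the median). Its expansin EXPA8 (AT2G40610) fell by 1.79 ± 0.23 and IAA29 by 1.15 ± 0.18. The largest rise of all was in AZI1 (AT4G12470), a lipid transfer-like protein of systemic immunity, at 5.25 ± 0.43 and 38.1-fold. The dark-inducible genes SEN1 (AT4G35770) and DIN10 (AT5G20250) fell by 2.27 ± 0.36 and by 1.75 ± 0.38, in a senescence and starvation list in which 2 of 14 rose and 4 fell, 2 and 4 adjusted over the list alone (adjusted p = 0.431 with an estimated correlation). GASA6, a gibberellin-responsive gene, fell by 1.92 ± 0.27 and J8, a chloroplast DnaJ protein, fell by 1.85 ± 0.30. In the starch and sugar list 5 of 11 rose and 1 fell, 5 and 1 adjusted over the list alone (adjusted p = 0.868 with an estimated correlation), led by the beta-amylase BAM3 at 1.58 ± 0.18. In all, 10724 genes passed as deposited, 10312 higher and 412 lower. With medians aligned it was 7590, 3474 higher and 4116 lower.

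In cold with high light a few photoprotective genes rose steeply. ELIP1 rose by 6.24 ± 0.52, 75.8-fold, ELIP2 by 5.55 ± 0.48 and GPT2 (AT1G61800), a plastid sugar phosphate transporter, by 4.28 ± 0.51. In that list 10 of 16 rose and 0 fell as deposited and adjusted over the list alone, and 4 rose and 1 fell relative to the median (adjusted p = 0.975 with an estimated correlation). Flavonoid genes rose in 14 of 16 cases with 0 falling as deposited and adjusted over the list alone, and 14 with 1 falling relative to the median (adjusted p = 0.435 with an estimated correlation), TT4 by 3.18 ± 0.22 and DFR by 2.97 ± 0.30. AZI1 rose by 5.70 ± 0.43 and KIN1 by 4.22 ± 0.46, while the cold regulon as a list had 10 of 17 rising and 1 falling, 10 and 1 adjusted over the list alone, and 7 and 3 relative to the median (adjusted p = 0.975 with an estimated correlation).

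Light harvesting genes fell under the same treatment in 2 of 14 cases as deposited and adjusted over the list alone and 11 relative to the median, with 0 rising (adjusted p = 0.449 with an estimated correlation). LHCB1.4 fell by 1.84 ± 0.27 and LHCB4.2 fell by 1.46 ± 0.34. Elongation genes fell too, with 1 rising and 6 falling of 13 as deposited and adjusted over the list alone and 0 and 12 relative to the median (adjusted p = 0.00535 with an estimated correlation, 0.221 relative to the median), among them EXPA8, which fell by 2.65 ± 0.23, and the growth regulator PIF4, which fell by 1.15 ± 0.14. GASA6 (AT1G74670) fell by 3.40 ± 0.27, 10.6-fold, the desaturase-like gene ADS1 fell by 2.48 ± 0.22, J8 fell by 2.44 ± 0.30 and BBX27 fell by 2.32 ± 0.17. Chaperones of the endoplasmic reticulum rose in 6 of 9 cases as deposited and adjusted over the list alone and 5 relative to the median, with 0 falling (adjusted p = 0.979 with an estimated correlation), BIP2 by 0.76 ± 0.21. Senescence genes fell in 5 of 14 cases and rose in 3, 4 and 1 adjusted over the list alone (adjusted p = 0.318 with an estimated correlation), NAP by -1.97 ± 0.24. The count was 13444 genes as deposited, 12963 higher and 481 lower. After centring it was 10013, 4421 higher and 5592 lower.

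A direct test of cold with high light against cold asks what the added light changed in the cold. Flavonoid genes were higher, 14 of 16 as deposited and adjusted over the list alone and 12 relative to the median with 0 lower (adjusted p = 0.0923 with an estimated correlation, 0.0250 relative to the median). TT7 (AT5G07990) was higher by 1.81 ± 0.28, DFR by 1.53 ± 0.30 and LDOX by 1.33 ± 0.27. ELIP1 and ELIP2 were higher by 1.80 ± 0.52 and 1.76 ± 0.48, in a photoprotection list with 5 of 16 higher and 0 lower, 5 and 0 adjusted over the list alone (adjusted p = 0.558 with an estimated correlation). The cold regulon was lower, 3 of 17 as deposited, 6 adjusted over the list alone and 7 relative to the median, with 0 higher (adjusted p = 0.0234 with an estimated correlation, 0.205 relative to the median). GOLS3, a galactinol synthase, differed by -1.64 ± 0.26, COR413IM1 by -1.56 ± 0.34, PORA by -1.49 ± 0.26 and GASA6 by -1.48 ± 0.27. In the thermomorphogenesis list 2 of 13 were lower, 2 adjusted over the list alone, EXPA8 by -0.86 ± 0.23 (adjusted p = 0.0923 with an estimated correlation). There were 3621 genes as deposited, 3498 higher and 123 lower. Relative to the median it was 629, 320 higher and 309 lower, and 541 with quantile normalization. Without cold end-point replicate 3 the count was 442, without cold with high light replicates 1 or 3 it was 1302 or 2361, and in a fit on these 6 libraries it was 5723.

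Drought brought the broad rise of abscisic acid genes that mark water shortage. All 19 members of that list rose as deposited, relative to the median and adjusted over the list alone (adjusted p = 0.154 with an estimated correlation). RD29B (AT5G52300, also LTI65) rose by 9.23 ± 0.80, 601-fold, the dehydrin RAB18 (AT5G66400) by 8.49 ± 0.62, TSPO by 7.96 ± 0.82 and the phosphatase HAI1 by 7.67 ± 0.63. HSFA6A (AT5G43840), a heat shock factor, rose by 10.07 ± 0.61, the malic enzyme NADP-ME1 (AT2G19900) by 8.99 ± 0.46 and LEA4-5 (AT5G06760), a late embryogenesis abundant protein, by 8.16 ± 0.72. The cold regulon rose in 14 of 17 cases and fell in 0 as deposited, 14 and 0 adjusted over the list alone and 12 and 2 relative to the median (adjusted p = 0.580 with an estimated correlation), LTI30 by 6.09 ± 0.48 and KIN1 by 6.04 ± 0.46. Heat shock genes rose without added heat, 15 of 16 as deposited and adjusted over the list alone, and 13 with 1 falling relative to the median (adjusted p = 0.655 with an estimated correlation), HSP70-4 by 4.65 ± 0.47.

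Cell division genes fell in drought, 11 of 13 as deposited and adjusted over the list alone and 13 relative to the median, with 0 rising (adjusted p = 0.123 with an estimated correlation). TSO2, of nucleotide supply for DNA replication, fell by 1.41 ± 0.14 and CYCB1;2, a mitotic cyclin, fell by 1.38 ± 0.15. Among the largest falls were EXPA8 with -3.48 ± 0.23, the wall-modifying enzyme XTH6 (AT5G65730) with -3.20 ± 0.20, GASA6 with -3.16 ± 0.27, FLA9 with -2.91 ± 0.22 and the growth regulator HBI1 (AT2G18300) with -2.88 ± 0.23. The thermomorphogenesis list had 2 rising and 7 falling of 13, 2 and 7 adjusted over the list alone and 0 and 11 relative to the median (adjusted p = 0.0591 with an estimated correlation). Guard cell markers had 1 rising and 5 falling of 9, 1 and 5 adjusted over the list alone and 0 and 8 relative to the median (adjusted p = 0.123 with an estimated correlation), MYB60 by -1.31 ± 0.13. Pigment genes rose, 16 of 16 as deposited and adjusted over the list alone and 12 with 1 falling relative to the median (adjusted p = 0.578 with an estimated correlation), with the anthocyanin regulator MYB90 at 6.02 ± 0.68. Jasmonate genes rose in 13 of 15 cases with 1 falling, 13 and 1 adjusted over the list alone (adjusted p = 0.719 with an estimated correlation), VSP2 by 3.59 ± 0.37. Senescence genes rose in 9 of 14 cases with 1 falling, beside 11675 of all 19010 genes rising. Adjusted over the list alone it was 9 and 1 (adjusted p = 0.868 with an estimated correlation). The sugar transporter SWEET15 of that list rose by 7.78 ± 0.42. Starch and sugar genes rose in 9 of 11 cases with 1 falling, 9 and 1 adjusted over the list alone (adjusted p = 0.432 with an estimated correlation), GOLS2 by 3.79 ± 0.32. As deposited 13495 genes passed, 11675 higher and 1820 lower. Relative to the median there were 12826, 4802 higher and 8024 lower.

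Heat combined with drought changed more genes than any other end-point. All 19 abscisic acid genes rose by every count, adjusted over the list alone included (adjusted p = 0.318 with an estimated correlation), RD29B by 10.09 ± 0.80. Heat shock genes rose in 15 of 16 cases as deposited and adjusted over the list alone, and 15 with 1 falling relative to the median (adjusted p = 0.598 with an estimated correlation), the small chaperone HSP17.4 by 7.36 ± 0.71 and the stress regulator DREB2A by 5.09 ± 0.55. HIPP22 (AT1G22990) rose by 11.06 ± 0.78, GLYI7 (AT1G80160) by 10.84 ± 0.79, CSLG2 by 10.36 ± 0.90 and LEA7 (AT1G52690) by 10.27 ± 0.97. CYP71A15 (AT5G24950) stood at 13.24 ± 1.86 with an SD of 8.71 between its 3 stress libraries, at 9.08 as deposited without heat-drought replicate 3, and did not pass in a fit on the groups compared only. Senescence genes rose in 12 of 14 cases with 0 falling, 12 adjusted over the list alone and 11 relative to the median (adjusted p = 0.739 with an estimated correlation), SAG21 by 4.96 ± 0.66. Clock genes rose in 14 of 15 cases, 14 adjusted over the list alone and 12 with 1 falling relative to the median (adjusted p = 0.566 with an estimated correlation), FKF1 by 2.79 ± 0.35. Flavonoid genes rose in 12 of 16 cases with 0 falling as deposited and adjusted over the list alone, but 6 rose and 4 fell relative to the median (adjusted p = 0.975 with an estimated correlation). In the jasmonate list 12 of 15 rose and 2 fell as deposited and adjusted over the list alone, and 7 and 2 relative to the median (adjusted p = 0.868 with an estimated correlation).

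All 13 cell cycle genes fell in heat-drought relative to the median, 12 as deposited and adjusted over the list alone (adjusted p = 0.0598 with an estimated correlation), PCNA1 by -2.42 ± 0.13. Light harvesting genes fell in 8 of 14 cases as deposited and adjusted over the list alone and in 14 relative to the median (adjusted p = 0.566 with an estimated correlation), LHCB6 by -2.17 ± 0.38, and RBCS1B (AT5G38430), a small subunit of Rubisco, fell by 3.33 ± 0.28. Glucosinolate genes fell in 8 of 16 cases as deposited and adjusted over the list alone and in 15 relative to the median (adjusted p = 0.528 with an estimated correlation), CYP83B1 by -2.19 ± 0.19. Guard cell markers had 1 rising and 6 falling of 9, 1 and 6 adjusted over the list alone and 0 and 8 relative to the median (adjusted p = 0.0657 with an estimated correlation). EXPA8, XTH6, HBI1 and FLA9 were again among the largest falls, with -3.87 ± 0.23, -3.75 ± 0.20, -3.73 ± 0.23 and -3.36 ± 0.22. In the hypoxia list 7 of 13 rose and 1 fell, 7 and 1 adjusted over the list alone but 3 and 7 relative to the median (adjusted p = 0.979 with an estimated correlation), and alcohol dehydrogenase ADH1 rose by 4.98 ± 0.35. The count was 15184 genes as deposited, 12684 higher and 2500 lower. With medians aligned it was 14948, 6116 higher and 8832 lower.

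The interaction of heat with drought asks whether the combination differs from the sum of its parts. Glucosinolate genes were below the sum, 13 of 16 as deposited and 15 adjusted over the list alone and relative to the median, with 0 above (adjusted p = 0.210 with an estimated correlation), MAM3 by -1.78 ± 0.34. Cell cycle genes lay below it in 9 of 13 cases as deposited and adjusted over the list alone and 11 relative to the median (adjusted p = 0.0888 with an estimated correlation), CYCB1;2 by -0.99 ± 0.21. Flavonoid genes lay below it in 8 of 16 cases, 9 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation), LDOX by -1.96 ± 0.38. Jasmonate genes lay below it in 4 of 15, 4 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation), LOX2 by -2.72 ± 0.37. Above the sum were 4 of 16 heat shock genes, 4 adjusted over the list alone (adjusted p = 0.741 with an estimated correlation), such as HSP21, a chloroplast chaperone, at 1.24 ± 0.26. So were 5 of 14 senescence genes, 6 adjusted over the list alone (adjusted p = 0.601 with an estimated correlation), such as DIN10 at 2.33 ± 0.54. Single genes far above it were CYP71A15 at 10.95 ± 2.64, HIPP22 at 4.77 ± 1.1, ECP63 at 3.94 ± 1.39 and the ethylene synthesis gene ACS2 (AT1G01480) at 3.82 ± 0.52. Far below were NUDT24 at -5.84 ± 0.87 and the defence genes PCC1 at -4.38 ± 0.70, LURP1 at -3.86 ± 1.00 and ACD6 at -3.84 ± 0.69. Without heat-drought replicate 3, CYP71A15, HIPP22 and ECP63 stood at 6.16, 3.17 and 1.19 as deposited. In this comparison 2 of 16 salicylic acid genes were lower, 2 adjusted over the list alone (adjusted p = 0.601 with an estimated correlation). The count was 3042 genes as deposited, 2143 higher and 899 lower, and 3079 relative to the median, 1516 and 1563. In a fit on these 12 libraries 77 genes passed, and of the 8 genes named by rule only ACS2. Of 34 genes named by rule or taken as list examples, 28 lost their call in that fit. The count was 894 without heat-drought replicate 3, 1160 without drought replicate 2 and 5174 without drought replicate 3. It was 4587 without heat-drought replicate 1, 1815 without control replicate 1 and 1989 without heat replicate 3.

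Heat alone, at 27 °C, changed few genes. In the jasmonate list 4 of 15 rose with 0 falling, 5 adjusted over the list alone (adjusted p = 0.431 with an estimated correlation), the vegetative storage protein genes VSP2 (AT5G24770) by 1.79 ± 0.37 and VSP1 by 1.36 ± 0.33. The clock gene ELF4 (AT2G40080) rose by 1.37 ± 0.21, in a list with 1 of 15 rising, but 8 rising and 1 falling adjusted over the list alone (adjusted p = 0.352 with an estimated correlation). FMO GS-OX2, of glucosinolate side chains, rose by 0.91 ± 0.21 and RCI2A by 0.90 ± 0.22. ARR15 (AT1G74890), a response regulator of cytokinin signalling, fell by 0.80 ± 0.13, FIB2 fell by 0.93 ± 0.20, RL4 fell by 0.79 ± 0.17, and the amino acid transporter genes UMAMIT17 and UMAMIT12 fell by 0.75 ± 0.13 and by 0.72 ± 0.14. Of 19 abscisic acid genes 2 rose, 9 adjusted over the list alone (adjusted p = 0.318 with an estimated correlation). Of 17 cold regulon genes 3 rose, 10 adjusted over the list alone (adjusted p = 0.146 with an estimated correlation). No heat shock gene of 16 passed over all genes, and 2 rose adjusted over the list alone (adjusted p = 0.692 with an estimated correlation). There were 130 genes as deposited, 108 higher and 22 lower. After centring it was 152, 70 higher and 82 lower. Without control replicates 2 or 3 the count was 22 or 36, without heat replicate 1 it was 7. A fit on these 6 libraries gave 424, and of the 10 genes named by rule only ARR15 passed under every alternative.

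Heat with high light changed few genes as well. VSP2 rose by 1.84 ± 0.37, the beta-amylase BAM5 (AT4G15210) by 1.45 ± 0.23, ELF4 by 1.14 ± 0.21 and the lipase-like TLL1 by 0.92 ± 0.21. FKF1 stood 1.34 ± 0.35 above the control but passed only as deposited. RAV2 fell by 0.88 ± 0.18, THI2.2 fell by 0.74 ± 0.14, PKS4 fell by 0.60 ± 0.13 and TPPH fell by 0.60 ± 0.11, while ATCTH, at -0.72 ± 0.20, passed only as deposited. In the clock list 4 of 15 rose, 8 rose and 1 fell adjusted over the list alone, and 1 rose relative to the median (adjusted p = 0.566 with an estimated correlation). In the jasmonate list 2 of 15 rose, 6 adjusted over the list alone (adjusted p = 0.318 with an estimated correlation). As deposited 169 genes passed, 157 higher and 12 lower. Relative to the median it was 46, 30 higher and 16 lower. The count was 27 without control replicate 2, 17 without control replicate 3, 53 and 19 without heat with high light replicates 1 and 2, and 567 in a fit on these 6 libraries. For the interaction of heat with high light limma called 0 genes, with 1634 at an unadjusted p under 0.05, 1 relative to the median and 1 without a filter. The 1634 genes are more than 0.05 of the 19010 tested.

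High light alone raised some photoprotective genes. GPT2 rose by 2.58 ± 0.51, ELIP1 by 2.18 ± 0.52 and LHCB4.3 (AT2G40100), a light-harvesting protein, by 1.28 ± 0.17, and ELIP2 stood 1.53 ± 0.48 above the control but passed only as deposited. In the photoprotection list 5 of 16 rose and 0 fell, 5 and 0 adjusted over the list alone and 3 and 0 relative to the median (adjusted p = 0.528 with an estimated correlation). Flavonoid genes rose in 7 of 16 cases, 13 adjusted over the list alone and 2 relative to the median, with 0 falling (adjusted p = 0.397 with an estimated correlation), TT4 by 0.95 ± 0.22. TBL26 rose by 1.19 ± 0.19. The auxin gene IAA29 (AT4G32280) fell by 0.94 ± 0.18, in a thermomorphogenesis list with 3 of 13 falling, 5 adjusted over the list alone, and 0 rising (adjusted p = 0.00126 with an estimated correlation, 0.145 relative to the median). GOLS2 fell by 1.31 ± 0.32 and ADS1 fell by 1.09 ± 0.22, and SEN1 and GASA6, at -1.35 ± 0.36 and -0.99 ± 0.27, passed only as deposited. In the starch and sugar list 2 of 11 rose and 1 fell, 5 and 2 adjusted over the list alone (adjusted p = 0.845 with an estimated correlation). In the jasmonate list 3 of 15 rose as deposited, 6 adjusted over the list alone and 0 relative to the median (adjusted p = 0.451 with an estimated correlation). As deposited 658 genes passed, 574 higher and 84 lower. Relative to the median there were 208, 77 higher and 131 lower. The count was 1569, 21 and 27 without control replicates 1, 2 and 3, and 110, 409 and 123 without high light replicates 1, 2 and 3, and a fit on these 6 libraries gave 1039.

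In high humidity some genes of the drought and cold responses fell. GOLS2 (AT1G56600) fell by 2.36 ± 0.32, P5CS1 (AT2G39800), of proline synthesis, fell by 1.78 ± 0.26 and RD20 fell by 1.72 ± 0.35. Abscisic acid genes fell in 4 of 19 cases, 9 adjusted over the list alone and 8 relative to the median, with 0 rising (adjusted p = 0.213 with an estimated correlation). Cold regulon genes fell in 4 of 17, 8 adjusted over the list alone and 5 relative to the median (adjusted p = 0.229 with an estimated correlation), COR15B by -2.45 ± 0.48. Flavonoid genes fell in 8 of 16 cases, 9 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation), LDOX by -1.65 ± 0.27 and DFR by -1.64 ± 0.30. PORA, of chlorophyll synthesis, fell by 1.78 ± 0.26. MIOX2 (AT2G19800), an inositol oxygenase, rose by 3.43 ± 0.23, the dark-inducible DIN10 by 2.81 ± 0.38 and ERD5, of proline breakdown, by 2.62 ± 0.33. BT2 and GDPD2, at 3.65 ± 0.99 and 2.84 ± 0.69, rose with SDs of 4.85 and 3.36 between the 3 humidity libraries, and did not pass in a fit on the groups compared only, nor did DIN10 and ERD5. Without humidity replicate 3, BT2 and GDPD2 stood at 0.90 and 0.96 as deposited. In the senescence list 2 of 14 rose, 3 adjusted over the list alone (adjusted p = 0.835 with an estimated correlation). In the hypoxia list it was 2 of 13, 2 adjusted over the list alone (adjusted p = 0.673 with an estimated correlation). Among chloroplast-encoded genes it was 5 of 62, 6 adjusted over the list alone (adjusted p = 0.582 with an estimated correlation). In all, 1095 genes passed as deposited, 852 higher and 243 lower. With medians aligned it was 1120, 680 higher and 440 lower. The count was 601 and 509 without control replicates 2 and 3, 508 without humidity replicate 3, and 575 in a fit on these 6 libraries.

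**Figure D2:**
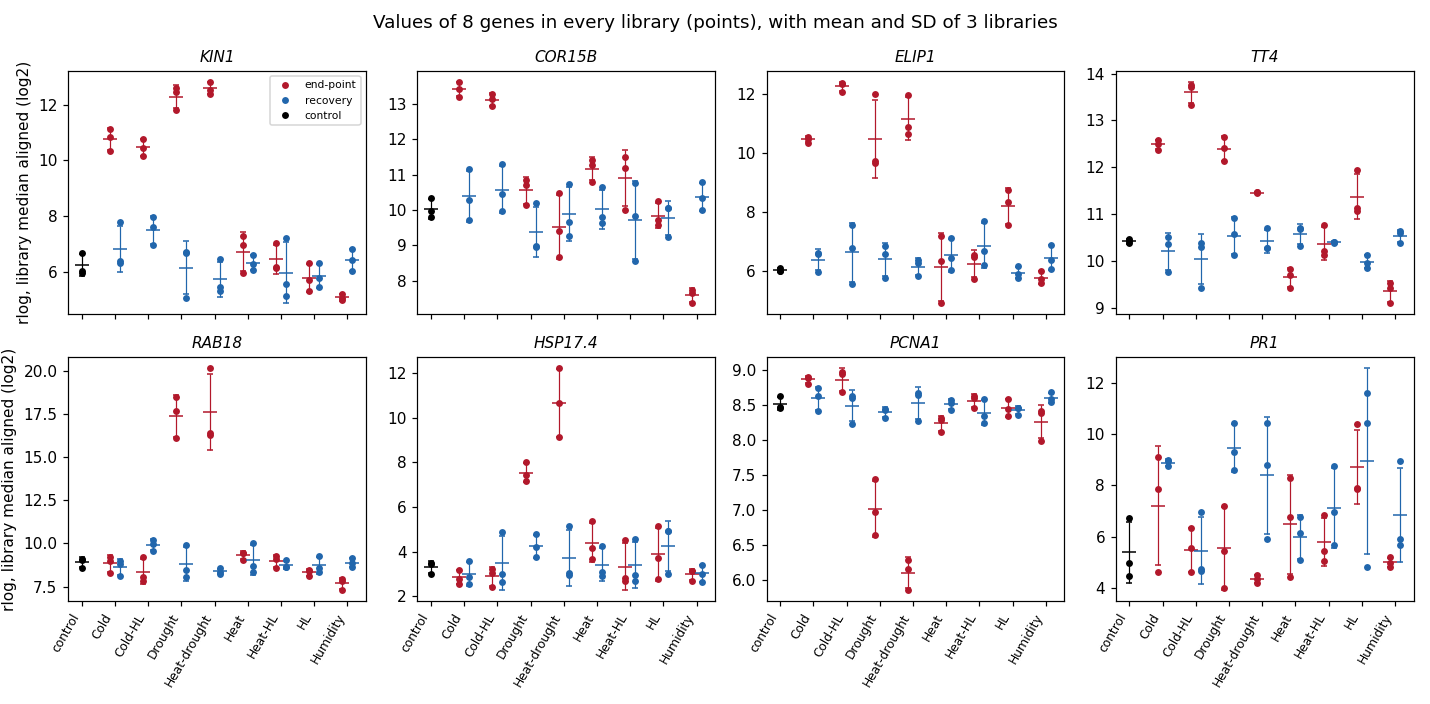
Values of 8 genes on the log2 rlog scale with library medians aligned (y axis) in control, end-point and recovery libraries of each stress (x axis), with points for libraries and bars for the mean and SD of 3. KIN1 rose by 4.53 in cold and 6.04 in drought, TT4 by 3.18 in cold with high light, and PCNA1 fell by 2.42 in heat-drought, while PR1 ran from 4.83 to 11.6 between the libraries of recovery from high light.

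After 3 days of recovery, limma called 0 genes against the control for each of the 8 stresses, as deposited and relative to the median. At an unadjusted p under 0.05 there were 109 genes in recovery from cold, 2066 from cold with high light, 2840 from drought, 111 from heat, 179 from heat-drought, 117 from heat with high light, 1614 from high light and 152 from humidity. In drought recovery the mean of salicylic acid defence genes relative to the median was 1.39 above the control, and 16 of 16 passed adjusted over the list alone, with 0 over all genes (adjusted p = 0.650 with an estimated correlation). Of 9 genes of endoplasmic reticulum folding 9 passed there over the list alone and 0 over all genes (adjusted p = 0.479 with an estimated correlation). After heat-drought the mean of the salicylic acid genes was 0.99 above the control with 0 of 16 passing either way (adjusted p = 0.358 with an estimated correlation), and it rests mostly on replicate 3, at 8.65, with the others at most at 6.99. In recovery from high light the mean of the salicylic acid genes relative to the median was 1.27 above the control and 14 of 16 passed as deposited adjusted over the list alone (adjusted p = 0.479 with an estimated correlation). This rests on replicates 2 and 3, with list means relative to the median of 8.65 and 8.21, while replicate 1, at 6.41, lay within the controls, at 6.27 to 6.86. In recovery from cold with high light 13 of 14 light harvesting genes were lower adjusted over the list alone and 0 over all genes, which rests on replicate 2, a library that stood apart. Their mean there was -2.60 relative to the control, but 0.12 and 0.09 in replicates 1 and 3. No list passed camera with an estimated correlation, the smallest adjusted p = 0.151 being that of thermomorphogenesis in drought recovery, and 43 of 168 passed with the preset correlation. Fits on the libraries of the 2 groups compared gave 486 genes in drought recovery, 450 higher and 36 lower, or 802 relative to the median, 408 and 394, and 27 in cold with high light, 8 in cold, 6 in humidity, 1 in heat and 0 in the other 3. Without replicate 3 of recovery from cold with high light 837 genes passed there, and without replicate 1 of recovery from high light 151.

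**Figure D3:**
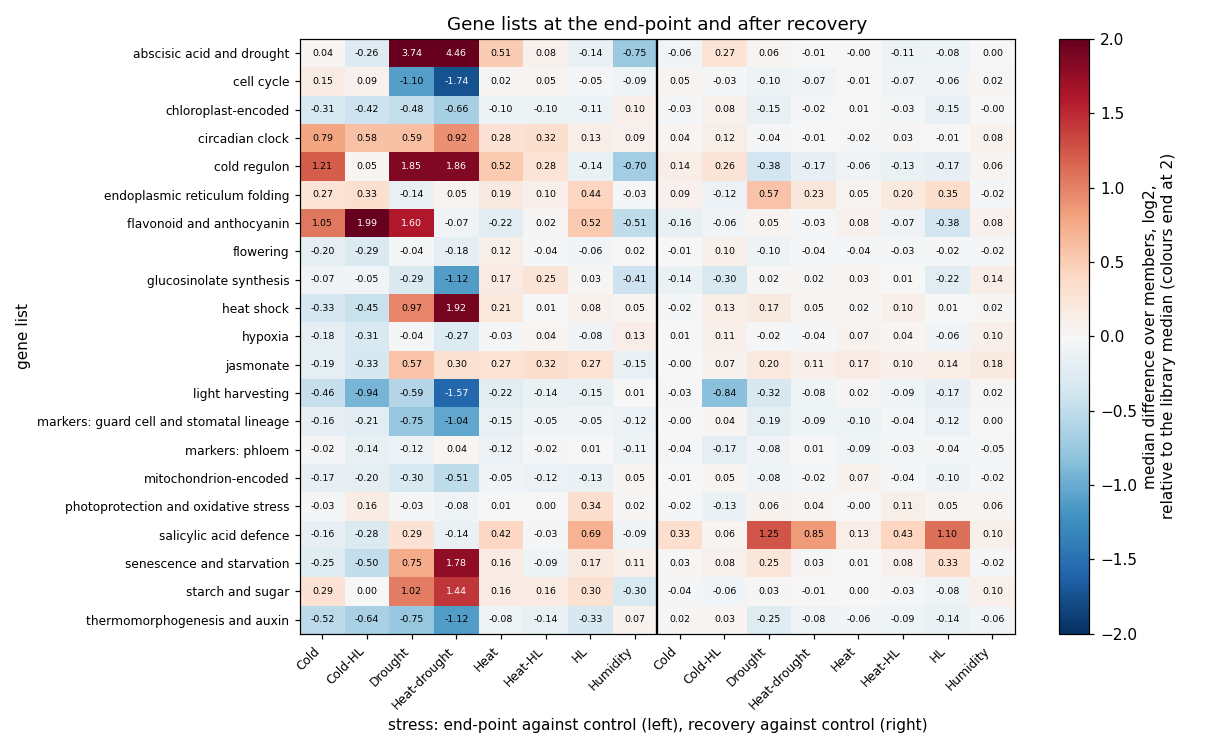
Median difference from the control over the members of each gene list (rows) relative to the library median, on the log2 scale, at the end-point (left columns) and after recovery (right columns) of each stress, with colours that end at 2. The median of abscisic acid genes was 3.74 in drought and 4.46 in heat-drought and 0.06 and -0.01 after recovery, whereas that of salicylic acid genes was -0.14 at the end-point of heat-drought and 0.85 after recovery.

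**Figure D4:**
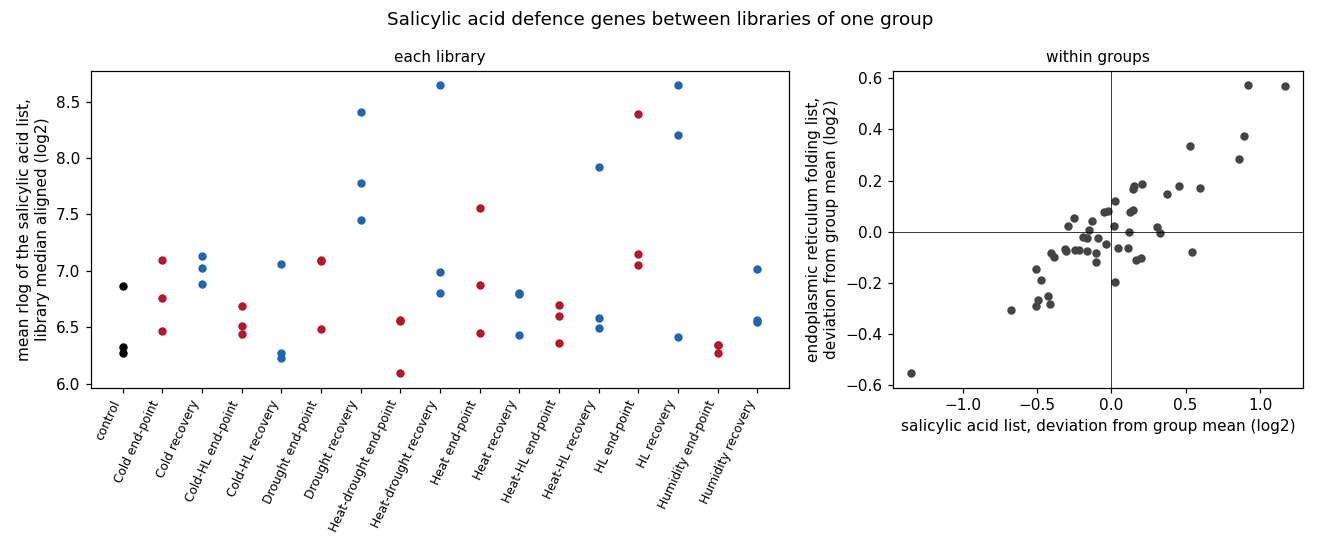
Mean of the salicylic acid defence genes per library on the log2 rlog scale for each group (left, with control in black, end-points in red and recoveries in blue), and its deviation from the group mean against that of the genes of endoplasmic reticulum folding (right), 51 libraries with medians aligned. The deviations correlated with r = 0.871 (permutation p = 2e-05), and the widest range within a group was 2.24, in recovery from high light.

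The test of recovery against end-point compares the groups of a stress directly, without the controls. Stress began on day 12 in the recovery setup and on day 15 in the end-point setup. The recovery plants were not sampled at the end of their own stress. A difference can therefore hold the age at which the stress was given as well as the return. In cold, KIN1 was lower in recovery by -3.93 ± 0.46, ELIP1 by -4.09 ± 0.52 and AZI1 by -4.41 ± 0.43, and SEN1, GASA6 and DIN10 were higher by 2.08 ± 0.36, 1.98 ± 0.27 and 1.94 ± 0.38. The cold regulon was lower in 15 of 17 cases, 15 adjusted over the list alone and 11 relative to the median (adjusted p = 0.608 with an estimated correlation). The thermomorphogenesis list had 5 of 13 higher and 1 lower as deposited and 12 and 0 relative to the median (adjusted p = 0.00927 with an estimated correlation, 0.239 relative to the median). In cold with high light ELIP1, ELIP2 and AZI1 were lower by -5.64 ± 0.52, -5.54 ± 0.48 and -4.99 ± 0.43. There GASA6, J8 and SEN1 were higher by 3.09 ± 0.27, 2.48 ± 0.30 and 2.43 ± 0.36. The thermomorphogenesis list had 7 of 13 higher and 1 lower (adjusted p = 0.0126 with an estimated correlation, 0.280 relative to the median). In drought HSFA6A, RAB18 and NADP-ME1 were lower by -9.87 ± 0.61, -8.60 ± 0.62 and -8.34 ± 0.46. All 19 abscisic acid genes were lower (adjusted p = 0.102 with an estimated correlation). EXPA8 was higher by 3.44 ± 0.23, the defence gene PR1 (AT2G14610) by 3.91 ± 1.31 and PCR1 by 3.43 ± 1.00. The calls of PR1 and PCR1 ended without drought end-point replicate 1 or drought recovery replicate 2. In heat-drought CYP71A15, LEA7 and HIPP22 were lower by -13.27 ± 1.86, -11.52 ± 0.97 and -11.39 ± 0.78, CYP71A15 by -9.09 as deposited without end-point replicate 3. There PCR1, PR1 and PCC1 were higher by 4.52 ± 1.00, 4.04 ± 1.31 and 4.02 ± 0.49, and PR1 did not pass without heat-drought end-point replicate 1 or recovery replicates 2 or 3. All 13 cell cycle and 13 of 14 light harvesting genes were higher relative to the median (adjusted p = 0.0752 and 0.594 with an estimated correlation).

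In recovery from humidity COR15B, GOLS2 and P5CS1 were higher than at the end-point by 2.79 ± 0.48, 2.17 ± 0.32 and 1.99 ± 0.26, and BT2, MIOX2 and BT5 lower by -3.67 ± 0.99, -3.41 ± 0.23 and -3.08 ± 0.55. Without humidity end-point replicate 3, BT2 and BT5 differed by -0.92 and -1.62 as deposited, and neither passed in a fit on these 6 libraries. In high light ELIP1, ELIP2 and DFR were lower by -2.27 ± 0.52, -1.85 ± 0.48 and -1.60 ± 0.30 and PORA higher by 1.07 ± 0.26, whereas SEN1 and BXL1, at 1.29 ± 0.36 and 1.03 ± 0.30, passed only as deposited. Flavonoid genes were lower in 12 of 16 cases in recovery from high light and 11 relative to the median (adjusted p = 0.0752 with an estimated correlation). The thermomorphogenesis list was higher there, 3 of 13, 4 adjusted over the list alone and 2 relative to the median (adjusted p = 0.0321 with an estimated correlation, 0.264 relative to the median). That call was lost without high light end-point replicate 1 (adjusted p = 0.137) and without recovery replicates 1 or 3 (adjusted p = 0.115 and 0.0727). In heat GOLS2 and RD29A were lower by -1.50 ± 0.32 and -1.44 ± 0.35, DIN11, MES18 and LHCB4.3 higher by 1.03 ± 0.25, 0.92 ± 0.18 and 0.89 ± 0.17, and FKF1, at -1.37 ± 0.35, passed only as deposited. DIN11 fell to 0.37 as deposited without heat recovery replicate 2. In heat with high light LHY and RAV2 were higher by 1.17 ± 0.25 and 0.81 ± 0.18, ELF4 and PWD lower by -1.03 ± 0.21 and -0.92 ± 0.20, and FKF1, at -1.47 ± 0.35, passed only as deposited. LHY fell to 0.67 as deposited without recovery replicate 3. Each of the 6, 6 and 5 genes named by rule in these recoveries from high light, heat and heat with high light failed to pass with 1 library or another left out.

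Counts of genes that differed between recovery and end-point were 10717 in cold, 363 higher and 10354 lower as deposited and 3947 and 3298 relative to the median. There were 12844 in cold with high light, 679 and 12165 or 6123 and 5156. Drought had 12405, 2001 and 10404 or 7472 and 4673. Heat-drought had 15055, 2473 and 12582 or 8723 and 6107. They were 1417 in humidity, 335 and 1082 or 567 and 868. High light had 602, 96 and 506 or 90 and 260. Heat had 168, 34 and 134 or 77 and 67. Heat with high light had 155, 4 and 151 or 8 and 27. In heat the count was 9 without end-point replicate 1, 31 and 21 without recovery replicates 2 and 3, and 685 in a groups-only fit. In heat with high light it was 59 and 13 without end-point replicates 1 and 2, 47 and 26 without recovery replicates 2 and 3, 35 relative to the median and 15 in a groups-only fit. In high light it was 278, 308 and 114 without end-point replicates 1, 2 and 3 and 148 and 117 without recovery replicates 2 and 3. In humidity it was 658 without end-point replicate 3 and 691 and 922 without recovery replicates 1 and 2.

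Among genes that had changed by at least 1 on the log2 scale at the end-point, nearly all met the definition of returned. The share was 99.1% of 665 genes in cold, 99.3% of 2117 in cold with high light, 96.2% of 2884 in drought, 99.3% of 6215 in heat-drought and 96.4% of 111 in humidity, with 6 of 8 genes in heat, 8 of 10 in heat with high light and 14 of 19 in high light. The others were undecided. No gene could be kept or crossed, since 0 genes passed against the control after recovery. Relative to the median the sets were smaller, with 96.3% of 216 genes returned in cold, 98.2% of 707 in cold with high light, 97.4% of 1945 in drought, 99.3% of 4017 in heat-drought and 95.2% of 105 in humidity. In heat it was then 6 of 10, in heat with high light 1 of 5 and in high light 9 of 13. In fits on the 3 groups of a stress, 12 genes were kept and 1 crossed in drought and 8 were kept in cold with high light. A gene counts as returned when its difference from the control does not pass, which does not show that it reached the control level. The end-point libraries that select a gene also enter the test of its return, which favours this class. The shares are therefore no measured rate of reversal. Its change at the end-point was measured in plants stressed from day 15, not in the recovery plants, which were stressed from day 12.

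With medians aligned, end-point differences from the control correlated across genes with r = 0.936 between drought and heat-drought. Unchanged groups that shared simulated controls gave 0.483 with an SD of 0.288. Those controls were drawn from residuals of all groups and do not hold the error of the 3 real ones. The covariance was 0.764 against 0.0107 with an SD of 0.00859. In both stresses 4433 genes rose and 7366 fell relative to the median where independent lists would share 1545 and 3728, and as deposited 11061 and 1592 where they would share 7790 and 239. For cold and cold with high light r was 0.919 against 0.522 with an SD of 0.178, the covariance 0.148 against 0.0108 with an SD of 0.00789. There 3211 rose and 3748 fell in both relative to the median where independent lists would share 808 and 1211, and as deposited 10072 and 299 where they would share 7032 and 10.4. Of 28 pairs of end-points 5 had a correlation above the simulated mean, only cold and cold with high light by over 2 SD, and 10 a covariance above it by over 2 SD. Among these 10 were heat with drought, at 0.0866 against 0.0117 with an SD of 0.00876, heat with heat-drought, at 0.109 against 0.0104 with an SD of 0.00747, and cold with high light paired with high light alone, at 0.0413 against 0.00992 with an SD of 0.00576. Genes are not independent replicates, the 3 controls cannot be split, and part of the excess may come from them. Between end-point and recovery the covariance was 0.0577 in drought, where simulations gave 0.00976 with an SD of 0.00744, and 0.0280 in high light, where they gave 0.00913 with an SD of 0.00473. In heat-drought it was 0.0236 against 0.0110 with an SD of 0.00787, and it lay below the simulated mean in the other 5 stresses, at -0.0122 against 0.0106 with an SD of 0.00672 in cold with high light. The correlation lay above the simulated mean only in high light, at 0.628 against 0.494 and less than the SD of 0.190 away, and below it in drought, at 0.298 against 0.468 with an SD of 0.225. No gene moved the same way in all 8 end-points by limma as deposited, with 0.000183 expected for independent lists and 0 in 20 simulations of unchanged groups. In at least 7 of 8 end-points 7 genes were higher as deposited, RAP2.4, TAG1, GPX6, PDC2, AT4G17140, AT4G36010 and AT5G39410, all chosen after their values were seen, and 0 were lower, with 0 in either direction relative to the median.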

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

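Of the tests in this part, the ratio of summed values, the share in the sum, the quartile test without the lowest quartile, the centring of drought recovery, the regrouping within watering and the ranges before and after centring were chosen only after the result was seen. The test of recovery against end-point shows that the effects in the recovery and end-point setups differ. It gave 10717 genes in cold, 12844 in cold with high light, 12405 in drought and 15055 in heat-drought. It gave 168 in heat, 155 in heat with high light, 602 in high light and 1417 in humidity. The interaction of heat with drought, with 3042 genes, and cold with high light against cold, with 3621, likewise test a difference between effects.

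Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. At each of the 8 end-points only 1 of the 10, the real one, gave as many genes, with the highest other count at 3291 in cold, 8373 in drought, 80 in heat-drought and 0 in the remaining 5. For recovery against the control all 10 of 10 gave as many as the real count of 0. For recovery against end-point it was 1 of 10 in every stress, the highest other being 2717 in cold with high light, 5836 in drought, 818 in heat-drought, 159 in high light and 0 in the remaining 4, and for cold with high light against cold 1 of 10 with 0. For the interaction of heat with drought 19 of 100 random regroupings of the 12 libraries gave as many genes, the highest 14553, but these carry the effect of drought into the contrast and decide nothing. With heat labels exchanged only within the droughted and within the watered libraries, 12 of 100 splits gave at least 3042 genes, the highest 8447. Of the 200 such splits, 20 leave the droughted libraries as they are and move only watered ones. Of the 100 drawn, 9 did so and all 9 reached 3042, so these splits decide nothing either, and whether chance explains this count stays open. For heat with high light 100 of 100 gave at least 0, the highest 511.

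The median over genes was higher than in the control at the end-points of drought and heat-drought, by 0.54 and 0.73. The test fixed before its result was seen took the median difference in all 4 quartiles of mean expression, with a span over 0.2 in both stresses as the bound against a single scaling factor per library, and the spans of 0.39 and 0.59 passed that bound. The bound overlooked that the rlog pulls low genes to their mean, which lowers their share of any factor, and without the lowest quartile the spans were 0.11 and 0.18, between the limits of 0.1 and 0.2, so a single factor stays open on the strength of a test added afterwards. A few abundant genes losing reads is argued against, since the median share of a gene in the sum of unlogged values of its library, without the 5 genes that held a value above 20, rose by at most 0.0688 of the rise of the median in the 6 libraries, whereas the sums of 1.34 and 1.56 times the control decide nothing alone, as the way the size factors were estimated is not known. More RNA per leaf is the biological alternative, with 78.0% of genes higher in heat-drought, and it cannot be told apart from scaling because no standard of known amount is in the values used here.

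In a fit on the 6 libraries of drought recovery and control, 486 genes differed although the fit over all groups called 0. The drought recovery libraries lay higher as a whole, by 0.12 in the median. As the cause of the count this level is argued against, since centring raised the count to 802. It went with the direction of the calls, which were 450 higher and 36 lower before centring and 408 and 394 after it. Control libraries that happen to be off for these genes stay open, as the median signed difference of the 802 genes was 0.389 in drought recovery and up to 0.594 of that, in high light, in the other recovery groups, and against the mean of those 7 groups it was still 0.286. A remainder of the drought response stays open too. Of the 802 genes 70.2% had the sign of the drought end-point, beside 67.9% of all genes tested. Among the 500 of them that also passed at the drought end-point, 399 had its sign. Unchanged groups that shared simulated controls gave 81.3%, but these hold no drought effect, so that value does not decide. Chosen after their values were seen, SAG13, GSTU4 and AOX1D stood 3.30 ± 0.39, 2.53 ± 0.21 and 2.16 ± 0.32 above the control in drought recovery and ADS1 at -0.68 ± 0.09. Each had the sign of its drought end-point difference and may be what is left of stress. The same held for GLYI7, CSLG2 and NIT2, at 2.25, 1.88 and 1.62, and for ARPN and BAM6, at -0.74 and -0.62. BAM6 had differed by only -0.03 at the end-point. Others went against that sign: PP2-A13, ICS2 and J20 stood at -0.72 ± 0.11, -0.60 ± 0.12 and -0.60 ± 0.09 in drought recovery. At the drought end-point these stood at 0.48, 1.35 and 0.83. None of the genes named here passed against the control in the fit over all groups, with limma's adjusted p from 0.0915 to 0.320.

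Salicylic acid defence genes differed between libraries of a single group. As deposited, PR1 ran from 4.70 to 11.6 in recovery from high light. The range of the list mean as deposited went from 0.04 at the end-point of humidity to 2.38 in recovery from high light. A factor that acts alike on libraries of the same number in all groups is argued against, since at most 10 of 17 groups deviated the same way for a number. That count pools both setups, so it cannot decide on a factor that acts within a setup only or oppositely in the setups. A compressed range of values is argued against too, with r = -0.140 to the interquartile range (permutation p = 0.377, rho = -0.03). Libraries that differ in scaling met the test fixed in advance, as the centred list mean followed the library median within groups with r = 0.627 (permutation p = 0.00026, rho = 0.60, p = 0.00073) over 51 libraries, and 0.571 without the 2 farthest. They are nevertheless argued against as the whole cause, since removing the library median left at least 0.757 of the range in each of the 9 groups with the widest ranges, 2.24 of 2.38 in recovery from high light, and what links the list to the median stays open. A difference between plants, for example in immune state, was not tested, as the labels name none.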

How the results depend on the processing

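The weight per group, the fit without the 2 libraries that stood apart and the groups-only fits of the combinations were chosen after seeing the data, and except where fewer libraries or genes are the construction, the cause was not tested. A mean rlog of at least 5 and limma without trend and robust variances moved 0 of 27 counts by over 1.5 times. Of 327 combinations of a gene and a comparison, named by rule or taken as list examples, 193 passed under every alternative. With 1 library or another left out 19 of 21 failed at the end-point of high light, 15 of 17 in heat, 12 of 13 in heat with high light and 12 of 25 in humidity. So did 13 of 34 for heat by drought and 5 of 15 for cold with high light against cold. In groups-only fits 71 of the 327 failed, among them 28 of 34 for heat by drought. At the end-points of humidity, high light and heat it was 11 of 25, 9 of 21 and 5 of 17. SLAC1 turned under centring, to -0.017 in drought and -0.040 in heat-drought. Centring gave 46 genes for heat with high light, 208 for high light, 35 and 350 for their recovery against end-point, 1 for the interaction of heat with high light and 629 for cold with high light against cold. It gave returned shares of 96.3%, 98.2%, 97.4% and 20% in cold, cold with high light, drought and heat with high light. There were 0 lists passing for end-points and for recovery against end-point, where 3 and 3 had passed, with 7 lists losing their call. Quantile normalization gave 5951, 7903, 500, 68, 343 and 1755 genes at the end-points of cold, cold with high light, heat, heat with high light, high light and humidity. It gave 5 in drought recovery. For recovery against end-point it gave 5506, 7970, 498 and 97 for cold, cold with high light, heat and heat with high light. It gave 541 for cold with high light against cold and returned shares of 95.1%, 97.7%, 97.3% and 99.0% in cold, cold with high light, drought and heat-drought. Groups-only fits gave 424, 567, 1039 and 575 at the end-points of heat, heat with high light, high light and humidity. They gave 8, 27, 486, 1 and 6 in recovery from cold, cold with high light, drought, heat and humidity. They gave 685 and 15 for recovery against end-point of heat and heat with high light, 77 for heat by drought and 5723 for cold with high light against cold. Kept shares were 0.379% and 0.416% in cold with high light and drought, and the returned share was 93.8% in high light. A weight per group gave 515, 463 and 2028 at the end-points of heat, heat with high light and high light. It gave 2 and 1 in recovery from drought and humidity and 1268 and 1268 for recovery against end-point of heat and high light. It gave 1414 and 1 for the interactions with drought and high light, 5577 for cold with high light against cold. Returned shares were 98.3%, 99.0% and 35.7% in cold with high light, heat-drought and heat with high light, with 1 gene in all 8 end-points. Without the 2 libraries that stood apart the values were 346, 345 and 1415 at the end-points of heat, heat with high light and high light. They were 2 in drought recovery and 369, 386 and 1107 for their recovery against end-point. Heat by drought gave 1358, and returned shares were 99.7% and 99.0% in cold with high light and heat-drought. Without a filter 5 genes passed in recovery from cold with high light, 107 for recovery against end-point of heat and 1 for heat by high light. Without a minimum difference returned shares were 92.3%, 90.09%, 86.5%, 96.2% and 84.3% in cold, cold with high light, drought, heat-drought and humidity. In at least 7 of 8 end-points 7 genes passed. With the preset correlation 76, 43, 77, 17 and 11 lists passed for end-points, recovery, recovery against end-point, interactions and cold with high light against cold.

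Replicate numbers are not taken to pair the samples: in 3 of 24 pairs of groups all 3 same-number correlations were above 0.1, and over all pairs they averaged -0.0176 against 0.0110 for different numbers. The 3 were control with the end-points of heat (0.369, 0.157 and 0.365), heat with high light (0.431, 0.205 and 0.211) and high light (0.420, 0.177 and 0.304), a hint of pairing there from the data and not from the labels. With the replicate block the counts were 248 and 256 at the end-points of heat and heat with high light, 2 in drought recovery. They were 267 and 323 for their recovery against end-point and 2 in all 8 end-points, with 100% returned in heat with high light and 9, 5 and 1 lists for end-points, recovery against end-point and interactions.

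With a replicate left out, counts ranged from 7 to 158 in heat, 17 to 167 in heat with high light, 21 to 1569 in high light and 508 to 1142 in humidity at the end-point. They ranged over 0 to 837, 0 to 2 and 0 to 151 in recovery from cold with high light, drought and high light. For recovery against end-point they were 9 to 189, 13 to 140, 114 to 646 and 658 to 1356 in heat, heat with high light, high light and humidity. They ranged from 894 to 5174 for heat by drought, 0 to 1 for heat by high light, 442 to 3848 for cold with high light against cold, and 0 to 2 for genes in all 8 end-points. Returned shares ranged from 98.0% to 99.5% in cold, 88.7% to 99.6% in cold with high light, 94.7% to 97.3% in drought, 12.5% to 100% in heat, 98.5% to 99.7% in heat-drought, 0% to 81.8% in heat with high light, 44.7% to 100% in high light and 89.1% to 100% in humidity. Kept shares ranged from 0% to 0.520% in cold with high light and 0% to 19.05% in high light. Lists passing ranged from 3 to 6 for end-points, 2 to 4 for recovery against end-point and 0 to 1 for interactions. The depth of the libraries is unknown, so what depth limits was not assessed.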

Other observations

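Partial correlations given the library median were chosen only after the first correlations were seen. Some lists were not described above. Of 5 flowering genes 0 rose and 1 fell in cold, SOC1 at -0.64 ± 0.12 (adjusted p = 0.566 with an estimated correlation), while 4 rose in drought and 4 in heat-drought as deposited. In drought 1 rose and 1 fell relative to the median, and in heat-drought 2 rose and 2 fell (adjusted p = 0.802 and 0.826 with an estimated correlation). Phloem markers had 3 of 5 rising in cold as deposited but 1 rising and 1 falling relative to the median (adjusted p = 0.991 with an estimated correlation), SWEET12 by 0.86 ± 0.18, and in heat-drought 5 of 5 rose as deposited, and 2 rose and 1 fell relative to the median (adjusted p = 0.802 with an estimated correlation). Mitochondrion-encoded genes had 4 of 14 rising in cold as deposited, and 2 rising and 5 falling relative to the median (adjusted p = 0.923 with an estimated correlation), and in cold with high light 12 rising as deposited, and 2 rising and 7 falling relative to the median (adjusted p = 0.975 with an estimated correlation). Chloroplast-encoded genes had 11 of 62 rising in cold as deposited, but 3 rising and 36 falling relative to the median (adjusted p = 0.574 with an estimated correlation). Relative to the median 45, 54 and 56 of them fell in cold with high light, drought and heat-drought, with 3, 0 and 0 rising, where 12, 8 and 11 rose and 0, 3 and 6 fell as deposited (adjusted p = 0.566, 0.586 and 0.586 with an estimated correlation). That most of them fell is thus seen only after centring. Of the marker lists too small to test, STM and KNAT1 of the shoot meristem passed as higher in 2 and 4 of 8 end-points as deposited and in 0 relative to the median, where each was lower in 1. PYK10 of the root passed as higher in 1 and lower in 2, and in 1 and 3 relative to the median. The flower genes AG and SEP3 passed as higher in 0 and 2 as deposited, and as lower in 4 each relative to the median, with group means of at most 3.78 and 4.07. At means this low centring alone can make a gene lower.

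Libraries of the same group that had higher salicylic acid genes also had higher genes of other lists. Over 51 libraries, deviations from group means correlated with those of endoplasmic reticulum folding with r = 0.871 (permutation p = 2e-05, adjusted 0.0002; rho = 0.75), 0.815 without the 2 farthest libraries and 0.802 given the library median. For senescence genes r was 0.781 (permutation p = 1e-05, the smallest that the permutations can give, adjusted 0.0002; rho = 0.77), 0.725 without the 2 farthest and 0.693 given the median. For heat shock genes r was 0.673 (permutation p = 0.00012, adjusted 0.0006; rho = 0.69), 0.665 without the 2 farthest and 0.437 given the median. Of 20 lists tested, 10 had an adjusted p under 0.05, and 0 of their members are in the salicylic acid list. Some lists share members with each other, such as GOLS2 in those of abscisic acid and of starch and sugar. The most negative Pearson r was that of guard cell markers, -0.615 (permutation p = 0.0009, adjusted 0.00327; rho = -0.59), -0.546 without the 2 farthest and -0.284 given the median. Flowering genes had r = -0.522 (permutation p = 0.00098, adjusted 0.00327; rho = -0.53), chloroplast-encoded genes -0.476 (permutation p = 0.00483, adjusted 0.0107; rho = -0.45) and photoprotection genes 0.429 (permutation p = 0.0106, adjusted 0.0211; rho = 0.45). Given the median these were -0.301, -0.184 and 0.303, and without the 2 farthest -0.507, -0.381 and 0.397.

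A hypothesis was that defence and growth genes oppose each other within groups. The test fixed in advance asked for r under -0.4 with each of 3 growth lists and came out so, at -0.548 for thermomorphogenesis (permutation p = 0.00149, adjusted 0.00426; rho = -0.55), -0.475 for the cell cycle (permutation p = 0.00202, adjusted 0.00505; rho = -0.57) and -0.423 for light harvesting (permutation p = 8e-05, adjusted 0.000533; rho = -0.75). Without the 2 farthest libraries these were -0.597, -0.410 and -0.444. Given the library median, however, the partial r was only -0.08, -0.175 and -0.00414, so the relation may come from libraries that differ in their median, and the hypothesis is left open.

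A pair of libraries stood apart from their groups. Recovery from cold with high light replicate 2 had the lowest sum of unlogged values, 0.624 of the control mean. All 5 values above 20 in the 51 libraries used lay in heat-drought end-point replicate 3, among them CYP71A15 at 27.0 and RAB18 at 20.7. Their medians in the other libraries were 3.24 and 8.66. Without read counts these extreme values could not be checked.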
